A study of Mus musculus with 2 samples.

How the data were processed

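The series holds single-cell RNA counts of aortic leukocytes from ApoE-/- C57BL6/J mice on a chow diet or on WD. Per the labels' protocols, aortas were digested with enzymes, viable CD45+ cells were sorted by flow cytometry, cells of 10 aortas were pooled for each diet, and 1 library per diet was prepared with the 10x Genomics 3' v2 kit from up to 10,000 loaded cells. Per the series' design text, CD4+ T cells were picked by marker genes in the downstream computation, with no rule stated. The deposited matrices give unique molecular identifier (UMI) counts per gene and cell barcode, without normalization. Per the submitters' processing notes, reads were processed with Cell Ranger and STAR against mm10; the versions are not given in the sources used here. Raw reads were not used here.

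The chow diet file held 909 barcodes with 4608033 UMIs (1493 to 25141 per barcode, median 3722), and the WD file 2077 barcodes with 8782901 UMIs (1414 to 28099, median 3177). Both files list 27998 genes, of which 27645 matched the reference annotation by gene ID. The constant genes of the T cell receptor and of immunoglobulins are not among them, so 13 of the markers set for naming cell types and 4 list genes could not be read. Barcodes with under 200 genes (2 and 0) or with over 10% of UMIs from mitochondrial genes (11 and 16) were removed. Scrublet, run in each library through scanpy at an expected rate of 0.8% per 1000 barcodes (0.726% and 1.66%), called 4 and 5 barcodes, which were also removed. These calls, 0.440% and 0.241%, lie under the expected rates, so unseen doublets remain possible. Kept were 892 chow diet cells (median 3740.5 UMIs and 1280.5 genes) and 2057 WD cells (3184 and 1135). Cells with 3 or more UMIs of markers of 2 lineages made up 7.40% and 5.30% of kept cells, and 30.6% and 14.8% of conventional dendritic cell-like cells.

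Both libraries were clustered together in scanpy 1.11.5: counts were scaled to 10000 per cell and log transformed, 2000 variable genes were taken and scaled, and 30 principal components, 15 neighbours and the Leiden method at a resolution of 1.0 were used. No batch correction was applied, since library and diet are the same factor. Clusters were named by the marker set whose share of cells with a UMI stood highest over all cells; a name needed at least 3 markers detected in 20% of the cluster's cells and no other set with more of the 10 leading genes, and clusters short of this were left unnamed. After the clusters had been seen, those in which at least 50% of cells held a Dntt UMI were kept apart as unnamed, since the marker sets have no class for immature lymphocytes. CD4+ T cells are cells of T-like clusters with at least 1 Cd4 UMI and no Cd8a or Cd8b1 UMI. T-like cells were clustered again with 1000 variable genes, 15 components and a resolution of 0.8. Shares carry exact 95% intervals; where no cell held a UMI, the upper limit given is 3 counts of the total, which limits cells with a UMI and not cells expressing the gene.

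For each class with at least 50 cells in both libraries, UMIs were summed per library and scaled to the total of the class (CPM), and the WD over chow diet ratio was given an exact conditional 95% interval. Log2 ratios had 0.5 UMIs added to each library, scaled by that library's class total over the mean total of both libraries. A gene with 0 UMIs in 1 library is given as a lower bound on the ratio, from a floor of 3 counts. Sums over cells were used because cells of 1 library are not replicates, and with 1 library per diet no test across diets, p-value or count of changed genes was made. Shares of cells with a UMI of a lineage factor were read in all cells and after each cell was thinned to 1000 UMIs. B-like cells were read beside them as a measure of free RNA and misassigned reads. This measure fails for a factor that B-like cells express themselves. It may also count unseen doublets of B-like cells with T cells. Cd3e was found in 33.3% and 32% of the cells of the small B-like clusters 12 and 15, against 1.49% in cluster 10. Genes with at least 10 UMIs over both libraries were measured. Where cells were thinned before summing, this minimum was applied to the thinned counts, so thinned list medians can cover fewer members than the main ones. A set of 32 gene lists with 465 genes was written down, and each list's median log2 ratio was placed among 10000 random lists of the same size matched for UMI level in 20 bins, with the middle 95% as the range. Genes named in the text come from a fixed set, the 12 highest and 12 lowest in CD4+ T cells and the 8 highest and 8 lowest in other classes among genes with at least 30 UMIs whose interval excludes 1, up to 4 members of each list, and cluster-leading genes; some further list members and AY036118 were picked after their values had been seen. The markers, lists, definitions, comparisons, main settings and the first set of other settings were fixed before the data were examined.

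The precision depends on depth. A median CD4+ T cell held 3214.5 UMIs in the chow diet library and 2809 in the WD library, a B-like cell 2907 and 2457, a T-like cell 3395 and 2927, and a conventional dendritic cell-like cell 9293 and 7040. The median log2 ratio over all genes was -0.07 in CD4+ T cells, 0.01 in T-like cells and 0.02 in conventional dendritic cell-like cells, and it was -0.01 in CD4+ T cells under median-ratio scaling. The steps for CD4+ T cells were tested on simulated data: in 20 draws with 200 of 4306 genes changed 2-fold or 4-fold, the median estimate was -1.94, -0.96, 0.01, 0.98 and 1.98 for true log2 ratios of -2, -1, 0, 1 and 2, and between 96.7% and 97.6% of intervals held the true value. Of 100 unchanged lists of 12 genes 5 lay outside the random range, and of 100 shifted lists 73 did. The draws were independent Poisson counts, the model that the intervals assume. They therefore check the computation only. UMIs clumped in single cells and list genes expressed together were not simulated.

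The other settings fixed in advance were a minimum of 500 genes, a mitochondrial limit of 5% or none, Scrublet calls kept, resolutions of 0.5 and 1.5, 1000 and 4000 variable genes, another clustering seed, thinning to 750 or 1500 UMIs or none, minimums of 5 and 20 UMIs, 1 UMI added in place of 0.5, other scalings, the mean over cells, cells thinned before summing, subcluster resolutions of 0.5 and 1.2, and CD4+ T cells by a marker gate alone or by whole subclusters. Added after the results had been seen were readings without the Dntt clusters or with them counted as T-like, without cells of 2 lineages, without the top cell of each gene and without cluster 7, and the reading of macrophage-like, ILC2-like and Dntt cells, which lack 50 cells in the chow diet library or a name.

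Python 3.11.15 was used with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, scikit-image 0.26.0, pandas 2.3.3 and matplotlib 3.10.9.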

Results

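Aortic CD45+ cells of ApoE-/- mice were compared between 1 library from mice on a chow diet and 1 library from mice on WD, each made from 10 pooled aortas. After filtering, 892 chow diet cells and 2057 WD cells remained. Apoe itself was detected in 30 of 892 chow diet cells (38 UMIs, 8.39 CPM, interval 5.94 to 11.5) and in 70 of 2057 WD cells (90 UMIs, 10.3 CPM, 8.31 to 12.7). The 3' tag that was counted may lie outside the deleted part of the gene, so these counts do not check the genotype. Xist was abundant in both libraries (4755 and 9264 UMIs), while the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 UMIs and Uty had 1. Each diet has 1 library, so every difference is one between 2 libraries, and all intervals cover counting error only.

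B cells and macrophages made up larger parts of the WD library. B-like cells, marked by Cd79a, Ebf1 and Ms4a1, made up 19.2% of chow diet cells (171 cells, 16.6 to 21.9%) and 27.5% of WD cells (566 cells, 25.6 to 29.5%), a ratio of 1.44. Macrophage-like cells, led by C1qa, C1qc and Pf4, made up 5.04% (3.70 to 6.69%) and 9.82% (8.57 to 11.2%), a ratio of 1.95. With 1000 variable genes the share was 8.74% and 13.6%, where a cluster led by Spp1, Thbs1 and F10 also took this name. T-like cells were the largest class in the chow diet library at 27.7% (247 cells, 24.8 to 30.8%) and held 26.2% of the WD library (539 cells, 24.3 to 28.2%). Conventional dendritic cell-like cells were similar at 9.53% (7.68 to 11.6%) and 10.2% (8.89 to 11.5%), as were ILC2-like cells, led by Il5 and Csf2, at 4.71% and 4.57%. At a resolution of 0.5 conventional dendritic cell-like cells held 2.35% and 1.99%, since a cluster of 351 cells led by Cd209a and Ifitm1 was then left unnamed. NK-like cells held 2.02% and 1.51%, and neutrophil-like cells 0.561% and 0.875%. With a mitochondrial limit of 5% the NK-like share was 5.31% and 6.03%. There the NK-like cluster held 163 cells led by Klra7, and no separate cluster led by Klra7, Ly6c2 and Xcl1 was left. In the main clustering that cluster held 128 cells, was unnamed and had Cd3e in 58.6% of its cells. This rise is therefore one of cluster naming. Immature cells rich in Dntt and Rag1 formed 4 clusters that were left unnamed and held 23.9% of the chow diet library (213 cells, 21.1 to 26.8%) against 10.7% of the WD library (221 cells, 9.44 to 12.2%). Because shares add to 100%, this group bears on all others: with these clusters left out, the B-like share was 25.2% and 30.8%, the macrophage-like share 6.63% (4.87 to 8.77%) and 11.002% (9.61 to 12.5%), and the T-like share 36.4% (32.8 to 40.1%) and 29.4% (27.3 to 31.5%). Clusters outside every named class other than the Dntt clusters held 7.40% and 8.60%; 1 was led by Thbs1, F10 and Clec4e and another by Klra7, Ly6c2 and Xcl1.

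**Figure D1:**
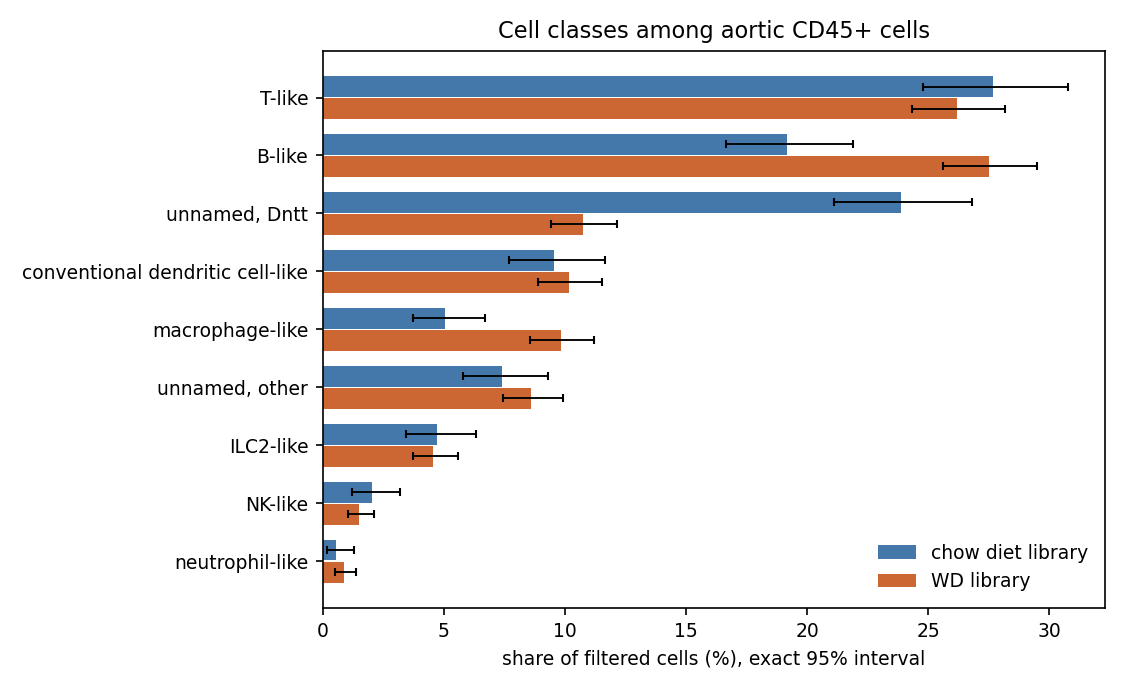
Share of filtered aortic CD45+ cells (percent) in each class, with exact 95% intervals that cover counting error only, for the chow diet library (blue, 892 cells) and the WD library (orange, 2057 cells). The B-like share was 19.2% and 27.5%, the macrophage-like share 5.04% and 9.82%, and the share of the Dntt clusters 23.9% and 10.7%.

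CD4+ T cells, taken as T-like cells with a Cd4 UMI and without a Cd8a or Cd8b1 UMI, were a smaller part of the WD library. They were 52 of 892 chow diet cells (5.83%, 4.38 to 7.57%) and 79 of 2057 WD cells (3.84%, 3.05 to 4.76%). Within T-like cells they held 21.1% (16.1 to 26.7%) and 14.7% (11.8 to 17.9%). In both cases the intervals overlap. With the Dntt clusters left out of the total, a setting added later, the shares were 7.66% (5.77 to 9.92%) and 4.30% (3.42 to 5.33%) of leukocytes. Those intervals do not overlap, so the overlap depends on the total used. Taking whole subclusters with more Cd4-positive than Cd8-positive cells raised the CD4+ T cell shares to 11.3% and 8.02% of leukocytes and to 40.9% and 30.6% of T-like cells. These subclusters also hold Cd8-positive cells. In the one led by Ccr7 (128 cells), 23.4% of cells had a Cd4 UMI and 22.7% a Cd8a or Cd8b1 UMI. In the one led by Tnfrsf4 (138 cells), the shares were 50% and 17.4%. A Cd4 UMI was also found in 5.26% of chow diet and 2.47% of WD B-like cells. By cluster, over both libraries, it was 0.995% in cluster 10 but 8.33% and 20% in the small B-like clusters 12 and 15. This background may therefore include doublets. T-like cells with both Cd4 and Cd8 UMIs were 7.29% and 1.86%, and median T-like depth was 3395 and 2927 UMIs. A Dntt UMI was found in 4.86% of chow diet and 1.67% of WD T-like cells. How far background, depth and any thymocytes among T-like cells shape the CD4+ T cell shares was not tested. The cluster led by Tnfrsf4, Tnfsf8 and Cd40lg, with Ctla4 and Icos among its leading genes, held 53.8% of chow diet CD4+ T cells (28 cells) and 38.0% of those of the WD library (30 cells). In the WD library the cluster led by Dapl1, Lef1 and Igfbp4 was the largest part at 44.3% (35 cells), against 36.5% (19 cells) in the chow diet library. The CD8-rich cluster 7, led by Gzmk, Ccl5 and Nkg7, held 7.69% (4 cells) and 16.5% (13 cells).

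Reclustering of T-like cells gave a subgroup with Tnfrsf4, Tnfsf8, Lmna, Cd4 and Cd40lg that held 51.9% of chow diet CD4+ T cells (37.6 to 66.0%) and 45.6% of WD CD4+ T cells (34.3 to 57.2%). A subgroup with Dapl1 and Igfbp4 held 23.1% and 16.5%, and one with Ccr7, Ifngr2 and Satb1 held 13.5% and 22.8%. Cells rich in the interferon-induced genes Rsad2 and Ifit1 were rare, at 2 chow diet cells and 1 WD cell. These subgroups depended on the settings. At a resolution of 0.5 those with Dapl1 and with Ccr7 were both matched to 1 subcluster that held 36.5% and 40.5%, and 12 of 24 results of the alternative settings left the main interval.

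Gata3, the factor of the T helper 2 lineage, was found in a larger part of chow diet CD4+ T cells. With every cell thinned to 1000 UMIs it was present in 7 of 52 cells (13.5%, 5.59 to 25.8%) and 4 of 79 cells (5.06%, 1.40 to 12.5%). The share was 0.585% and 0.353% in B-like cells, which serve as a background that may include doublets. The 2 thinned intervals overlap. Unthinned, Gata3 was present in 34.6% and 17.7% of CD4+ T cells and in 2.92% and 1.59% of B-like cells, at median depths of 3214.5 and 2809 UMIs in CD4+ T cells and 2907 and 2457 in B-like cells. Tbx21, the factor of the T helper 1 lineage, was present in 3.85% and 1.27% of thinned CD4+ T cells (1.17% and 0.177% of B-like cells), and unthinned in 11.5% and 8.86% (1.75% and 0.530% of B-like cells). Foxp3, the factor of regulatory T cells, was seen in 2 chow diet cells (3.85%) with and without thinning, and in 1 WD cell (1.27%) unthinned and 0 of 79 thinned, which allows a share of cells with a UMI of up to 3.80%; in unthinned B-like cells it stood at 0.585% and at 0 of 566, which allows up to 0.530%. Bcl6 had 0 cells in both libraries after thinning, and unthinned it was present in 1.92% and 6.33%, against 3.51% and 3.00% of B-like cells. B-like cells may express Bcl6 themselves, so their share is not a background for it. Unthinned Ifng was present in 15.4% and 15.2% of CD4+ T cells (2.34% and 1.41% of B-like cells). Unthinned Tbx21 and Gata3 were found in the same cell 3 times in the chow diet library and 2 times in the WD library, where independent detection would give 2.08 and 1.24.

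Among single genes, Ccl5, Ccl4 and Gzma were higher in the CD4+ T cells of the WD library, and Areg, Ikzf2 and Gata3 were higher in those of the chow diet library. Ccl5 had 258 UMIs in the chow diet library and 921 in the WD library (log2 ratio 1.49, ratio 2.81, interval 2.45 to 3.24) and was spread over 17 and 29 cells. Ccl4, a chemokine of activated lymphocytes, was 7.28-fold higher in the WD library (2.62 to 28.1; 4 and 12 cells). Gzma had 1 and 48 UMIs, a ratio of 37.8 (6.47 to 1523) that came from 4 WD cells. Klrd1, a receptor of NK and cytotoxic T cells, had a log2 ratio of 2.16 (3 and 19 UMIs). Ccl5 and Nkg7 lead cluster 7, which held more of the WD cells. With whole subclusters Ccl5 stood at -0.01, Ccl4 at -1.33 and Gzma at -1.45. Without cluster 7 Gzma stood at -1.68. Il17a, the cytokine of T helper 17 cells, had 0 UMIs in the chow diet library and 49 in the WD library, at least 12.9-fold more, but 39 of them lay in 1 of 2 cells. Retnla (log2 ratio 3.78) owed 40 of 42 WD UMIs to 1 cell and stood at -0.28 without it. The other genes highest in the WD library were Nsmce1 (2.34, 22 WD cells), Zcchc7 (1.38), Rbm42 (1.31), Tnrc6b (8 and 24 UMIs), Slfn1 (1.16, but -0.0009 with whole subclusters), Ankrd11 (1.11) and Mat2a (1.04).

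On the chow diet side, Areg, an epidermal growth factor family ligand made by tissue regulatory T cells, had 31 and 4 UMIs (log2 ratio -3.13; 6 and 2 cells). Ikzf2, which encodes Helios, had 33 and 11 UMIs (-1.88; 9 and 11 cells). Gata3 had a log2 ratio of -1.52 (37 and 16 UMIs) and -0.96 without its top cell. Il13 (34 UMIs, at least 14.4-fold more) and Ccl1 (41 UMIs, at least 17.4-fold more) came from 1 chow diet cell each. Rora stood at -1.40 (63 and 30 UMIs) and Itgb1 at -1.08 (82 and 49 UMIs). Furin (-1.62), Zfand5 (-1.64), Pdia6 (-1.74) and Cdipt (-1.50) were also lower in the WD library. Cxcl10 (-2.54), Gem (-2.40) and Hist1h2ap (-2.40) rested largely on 1 chow diet cell each and stood at -0.56, -0.94 and -0.32 without it, and whole subclusters turned Cxcl10 to 1.11 and Hist1h2ap to 0.40. Cd4, of which each of these cells had to hold a UMI, stood at 0.07. Cd3e stood at -0.44, Cd28 at -0.48, Ptprc at -0.32 and Tnfrsf18 at 0.11. Tbx21 (0.07; 6 and 8 UMIs) and Ifng (0.31; 12 and 19 UMIs, ratio interval 0.575 to 2.82) were not separated from 1 by counting error.

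**Figure D2:**
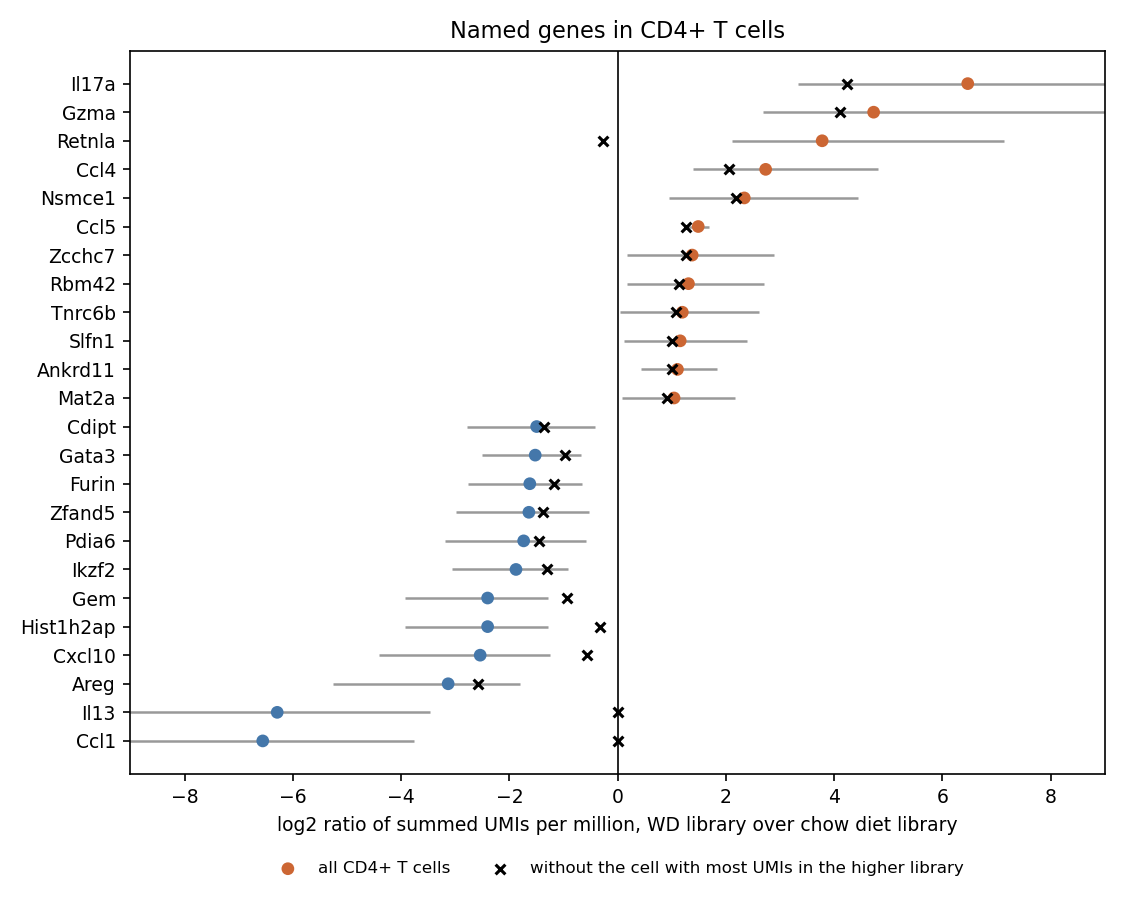
Log2 ratio of summed UMIs scaled to each class total (CPM), WD over chow diet library, in CD4+ T cells for the 12 genes with the highest and the 12 with the lowest ratio. Dots are orange where higher and blue where lower in the WD library, and lines are 95% counting intervals, some running past the axis. Genes with 0 UMIs in 1 library are placed with 0.5 UMIs, scaled by library total, added to each library. Crosses give the ratio without the cell with most UMIs in the higher library. Ccl5 moved from 1.49 to 1.27 without that cell, while Retnla moved from 3.78 to -0.28 and Cxcl10 from -2.54 to -0.56.

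Across gene lists, CD4+ T cells of the WD library were higher in naive and central memory genes and lower in activated and effector memory genes. Of 14 naive and central memory genes 11 were higher in the WD library, with a median log2 ratio of 0.46 against -0.31 to 0.15 for the middle 95% of matched random lists. Klf2 (0.46), Lef1 (0.59), Ccr7 (0.71) and Dapl1 (0.82), which mark cells that recirculate through lymph nodes, were each higher. The marker gate turned Lef1 to -0.17. Of 17 activated and effector memory genes 12 were lower (median -0.61, random range -0.24 to 0.12), among them Crip1 (-0.70), Lgals1 (-0.77) and S100a10 (-0.69). Both medians kept their sign in 12 of 12 planned settings but shrank in some. As a mean over cells they stood at 0.21 (naive) and -0.21 (activated), and thinning put the activated list at -0.23. Cytotoxic genes had a median of 0.68 (6 of 9 higher; random range -0.44 to 0.30), with Ccl5, Gzma, Klrd1 and Nkg7 (0.34) in front, and the T helper 1 list a median of 0.22 (10 of 14 higher; random range -0.36 to 0.20, outside it in 7 of 12 other settings fixed in advance), with Ccl5, Ccl4 and Nkg7 shared or leading and Stat4 at -0.96, or 0.13 with thinning. Without the cells of cluster 7 these medians were -0.41 and -0.30, and with whole subclusters -0.014 and -0.15. Both settings leave out cells grouped by genes of these lists, such as Ccl5 and Nkg7, so lower medians follow from the selection.

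Regulatory T cell genes had a median of -0.56 in CD4+ T cells (8 of 11 lower; random range -0.41 to 0.26), led by Areg and Ikzf2, with Tnfrsf4 at -0.71 and Klrg1 at 17 and 0 UMIs (at least 7.20-fold more in the chow diet library, 3 cells). The list lay within its random range under the marker gate (-0.037) and as a mean over cells (-0.14), and the marker gate turned Areg to 0.28, as whole subclusters turned Ikzf2 to 0.19. T helper 17 genes had a median of -0.59 (7 of 10 lower) but a mean of -0.02, since Il17a and Il21r (0.86) were higher while Rora and Tmem176b (-1.36) were lower; the marker gate turned the median to 0.33 and Tmem176b to 0.14, and thinning turned Il21r to -0.16. The T helper 2 list, with 4 genes measured, stood at -0.75, and at 0.19 without the top cell of each gene. Homing receptors were lower at -0.42, with Itgb7 at -0.56, Gpr183 at -0.89 and Cxcr4 at -0.81 but Ccr7 higher. The homing list turned to 0.18 under the marker gate and stood at 0.0065 as a mean over cells and -0.11 with whole subclusters. Interferon gamma response genes stood at -0.32 (13 of 15 lower), close to the bound of their random range (-0.31) and outside it in 4 of 12 other settings, with B2m at -0.21 and H2-D1 at -0.36. Other lists outside their random range overlap with those above or belong to other cell types: foam cell and Trem2 macrophage (-0.71, with Lgals3 at -1.36 shared with the activated list and Plin2 at -1.48), B-1 and innate-like B cell (-0.67, sharing Lgals1, Vim and Anxa2 with the activated list), follicular B cell (0.53, sharing Klf2 and Ccr7 with the naive list) and myeloid transcripts abundant in free RNA (median 0.45, mean -0.17, with Cd74 at 0.60, or -0.14 with whole subclusters, and Fcer1g at -2.15, and -0.82 without cells of 2 lineages). The 14 lists inside their range ran from -0.36 to 0.52: proliferation -0.36, inhibitory receptor -0.31, glycolysis -0.23, nuclear factor kappa B and tumour necrosis factor response -0.18, inflammatory macrophage -0.16, oxidative phosphorylation -0.10, tissue-resident memory -0.09, apoptosis -0.08, type I interferon response -0.06, immediate early and dissociation-induced -0.03, follicular helper T -0.01, T cell receptor 0.01, antigen presentation on MHC class II 0.18, and cholesterol efflux 0.52, in which all 4 measured genes were higher, Abcg1 (ratio 2.99, 1.08 to 10.3) among them.

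**Figure D3:**
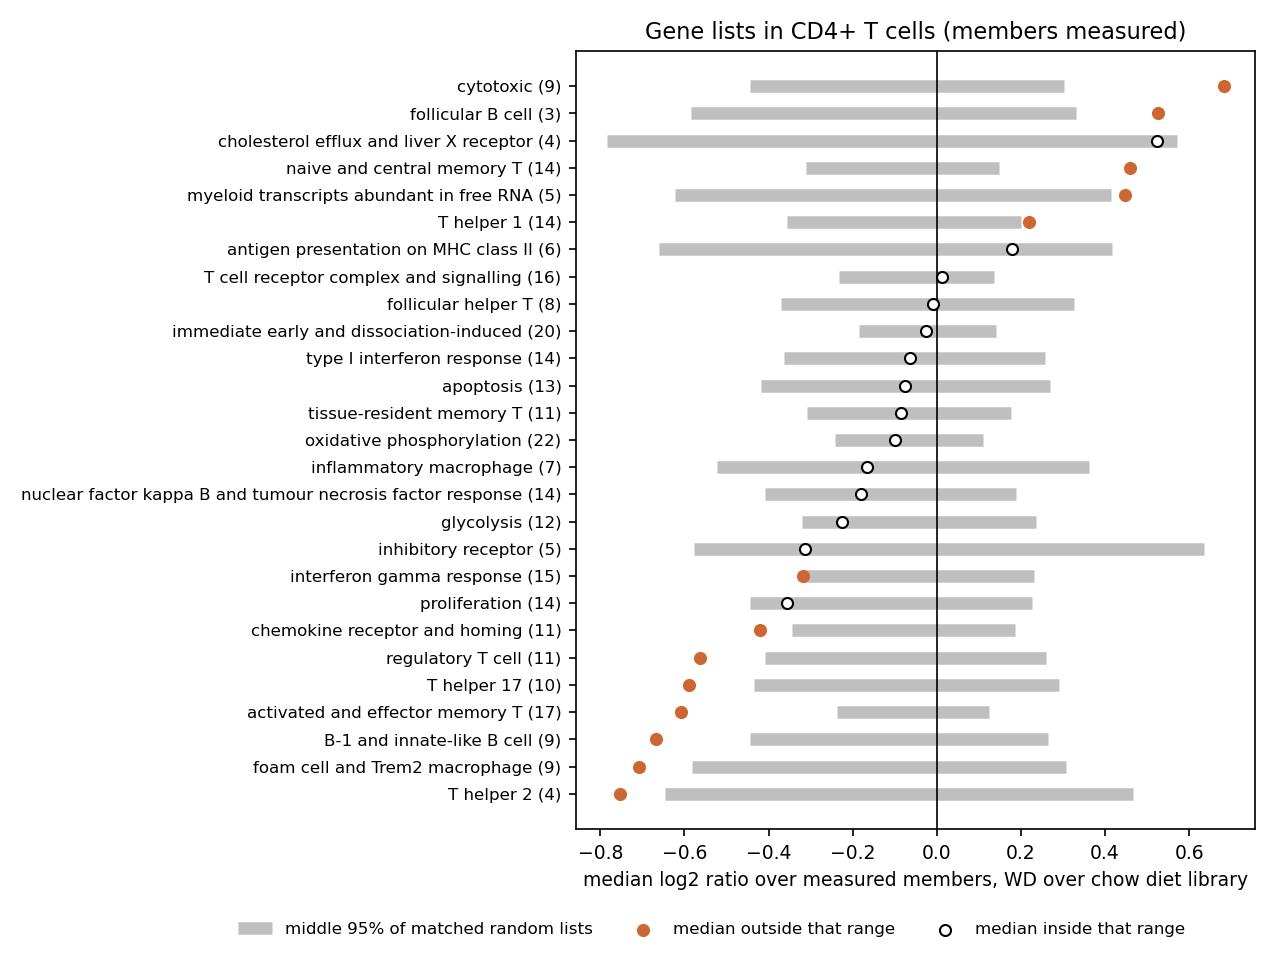
Median log2 ratio, WD over chow diet library, of each gene list in CD4+ T cells (circles, filled where the median lies outside the grey bar), against the middle 95% of random lists matched for size and UMI level (grey bars), with the number of genes measured in brackets. The naive and central memory list stood at 0.46 and the cytotoxic list at 0.68, and the activated list stood at -0.61 and the regulatory T cell list at -0.56.

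The T helper 2 list was lower in T-like cells of the WD library, in all 8 measured genes (median -1.72, random range -0.33 to 0.40): Gata3 at -0.95 (101 and 94 UMIs), Ccr4, a receptor for skin and type 2 homing, at -2.73, Il1rl1, the interleukin 33 receptor, at -2.48, Il4 at -2.52, and Il13 at 38 and 0 UMIs (at least 22.9-fold more in the chow diet library, with 34 UMIs in 1 of 4 cells). Thinning every cell to 1000 UMIs brought this median to -0.12. Type 2 genes also mark ILC2-like cells, which held 82 of 136 chow diet and 160 of 161 WD UMIs of Il13. Whether such cells lay among the T-like cells was not tested. Il17a had 0 UMIs in 247 chow diet cells and 147 in 13 of 539 WD cells, at least 27.1-fold more; 7 of the 13 cells lay in cluster 17, led by Cd163l1, which encodes the scavenger receptor SCART1 of gamma delta T cells. Il17f came from 1 chow diet cell (31 of 32 UMIs; -3.66, and 0.92 without it). The largest T-like cluster was cluster 9, led by Dapl1 and Lef1, in the chow diet library (97 of 247 cells) and the CD8-rich cluster 7 in the WD library (218 of 539 cells). Cluster 13, led by Tnfrsf4, Tnfsf8 and Ctla4, held 60 of 247 and 72 of 539 cells. Ccl5 (0.45) and Nkg7 (0.37) lead cluster 7 and were not read apart from the makeup of clusters.

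The cytotoxic list was higher in T-like cells of the WD library (median 0.44, 8 of 11 genes), with Ctsw at 0.54, Klrk1 at 0.55 and Gzma at -0.34 in all cells but 0.23 without its top cell. T helper 1 genes were higher at 0.27, with Ccl4 at 1.14 (215 and 858 UMIs). The cytotoxic and T helper 1 lists were not told apart from the larger share of cluster 7 (72 and 218 cells) among WD T-like cells. Ccl3 (1.33), Il1b (1.96) and Ccl4 put the inflammatory macrophage list at 0.30, whereas Cxcl2, a neutrophil chemokine, was 3.15-fold higher in the chow diet library (2.35 to 4.26). MHC class II genes (0.42) and myeloid transcripts abundant in free RNA (0.49) were higher, with Cd74 at 0.49 in both lists, and turned to -0.16 and -0.11 without cells of 2 lineages. Regulatory T cell genes (-0.51, 13 of 14 lower, with Tnfrsf4 at -0.73 and Klrg1 at -1.23), proliferation genes (-0.39; Pcna -0.72, Rrm2 -1.28, Ube2c -0.94 but 0.0024 without its top cell), activated and effector memory genes (-0.16; Lgals1 -0.31), immediate early and dissociation-induced genes (-0.12; Fosb -0.92 but Jun 0.38), the foam cell list (-0.28; Ctsz -0.79 but Abcg1 0.82) and the B-1 list (median -0.30, mean 0.06; Plac8 1.07) were lower. The lower regulatory and activated lists were not told apart from the smaller share of cluster 13 among WD T-like cells. Thinning turned the regulatory T cell list and Klrg1 to 0.043, the inflammatory macrophage list to -0.054, Il1b to -0.91, Kcnk5 to -0.11 and Ccl3 to -0.0098, and left immediate early genes at 0.0011. The proliferation list lay within its random range without cells of 2 lineages (-0.053) and without the top cell of each gene (-0.069). Apart from Il17a, the genes highest in the WD library were Krt83 (2.26), Taz (1.88), Smpd5 (1.87), Zfp322a (1.80), Zfp397 (1.76), Cerk (1.68) and Kcnk5 (1.66), and those lowest included Fdxr (-2.07), a mitochondrial reductase. Stfa3 (34 UMIs) and Ccl1 (41 UMIs) each came from 1 chow diet cell. The other 16 lists lay within their random ranges, between -0.22 and 0.14.

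B-like cells of the WD library were lower in immediate early and dissociation-induced genes, which also respond to tissue handling, and higher in targets of nuclear factor kappa B. Cluster 10, led by Ebf1 and Cd79a, held most of them in both libraries (135 and 468 cells). Of 20 such immediate early genes 17 were lower in the WD library (median -0.23), with Junb at -0.20, Hsp90aa1 at -0.36, Nr4a1 at -0.21, Dusp1 at -0.60 and Fosb at -0.82. Of 15 nuclear factor kappa B genes 12 were higher (median 0.22, and 0.13 within the random range as a mean over cells): Nfkbia, the inhibitor induced by the pathway, at 0.45, Relb at 0.29 and Ccl4 at 1.71 (39 and 366 UMIs, ratio 3.28, 2.35 to 4.69), whereas Tnf stood at -2.38 (12 and 6 UMIs). Transcripts of T cells and myeloid cells also differed among B-like cells. The T cell receptor list was lower (median -0.43, 14 of 16; Cd3g -1.09), as were the naive T list (-0.25; Tcf7 -0.82, Lef1 -1.06, Dapl1 -4.21), the tissue-resident memory list (-0.20; Crem -0.29 but Rgs1 0.44) and the myeloid free RNA list (-0.45; Lyz2 -1.59, C1qa -1.82), while the cytotoxic list was higher (0.63; Ccl5 0.59, Nkg7 0.63, Gzma 0.83). Thinning turned the T cell receptor list to 0.19, Cd3g to 0.33 and Gzma to -0.047. Without cells of 2 lineages, which were 10.5% and 5.83% of B-like cells, the myeloid list stood at -0.083 and the naive T list at -0.16, both within their random ranges.

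Mthfs, an enzyme of folate metabolism, was the gene with the most UMIs among those highest in WD B-like cells apart from Jchain (5 and 62 UMIs, 2.06, ratio 4.33, 1.76 to 13.8). Lepr, the leptin receptor, had 1 and 33 UMIs (3.23; 4 WD cells). Cox11 (2.47), Prmt7 (2.38), Cacna1s and Mcm4 (both 1.94) and Tmem41b (1.78) were higher as well, but thinning turned Mcm4 to -0.66. Jchain, a gene of antibody-secreting cells, stood at 1.79, but 717 of 833 WD UMIs came from 1 cell, and without it the log2 ratio was -1.05. Slpi (-4.27) and Ifng (-2.11) likewise rested on 1 chow diet cell and stood at 3.99 and 0.06 without it. Slc15a3 (-1.75), Haus2 (-1.48), Csf2rb (-1.42), a receptor chain for interleukin 3 and GM-CSF, and Cpsf3 (-1.38) were lower. The remaining 21 lists ran from -0.42 to 0.24 within their random ranges, the type I interferon list at -0.24 among them.

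Conventional dendritic cell-like cells of the WD library were higher in type I interferon response genes and lower in cell cycle genes. Of 18 interferon genes 17 were higher (median 0.66, random range -0.21 to 0.25), and the alternative settings left the median between 0.58 and 0.89. Bst2, which tethers budding virus, was at 0.71 (139 and 410 UMIs, ratio 1.63, 1.34 to 1.99), Isg15 at 0.60, Irf7 at 0.61, Rtp4 at 1.18, Zbp1 at 0.82 and Ifit3 at 1.42, with Ifi47 the exception at -0.36. Thinning turned Irf7 to -0.072. Ifit1 stood at 3.00, with 87 of 106 WD UMIs in 1 cell and 0.56 without it. Ifna2 and Ifnb1, the ligands, had 34 UMIs each in 1 WD cell and 0 in the chow diet library. Siglech, a receptor of plasmacytoid dendritic cells, stood at 3.46 (3 and 66 UMIs in 3 and 12 cells, ratio 12.2, 3.99 to 60.6), and Cox6a2 had 0 and 33 UMIs (6 cells, at least 6.09-fold more). Cluster 11, led by Cd209a and Ifitm1, held most cells of this class in both libraries.

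**Figure D4:**
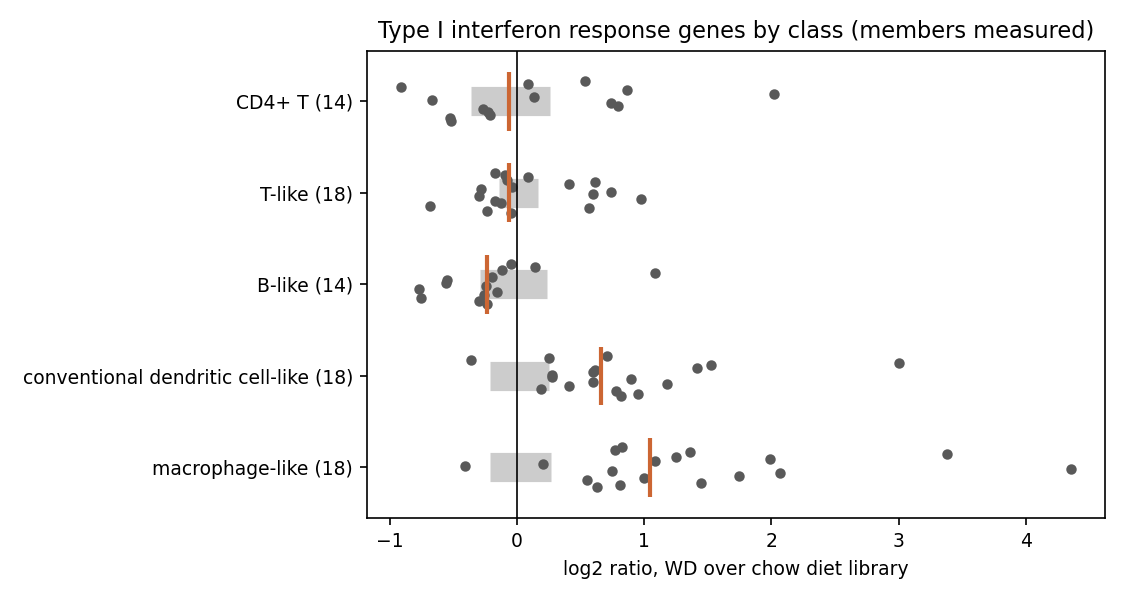
Log2 ratio, WD over chow diet library, of each measured type I interferon response gene (dots) with the list median (orange line) and the middle 95% of medians of matched random lists (grey bar) in each class; macrophage-like cells number 45 in the chow diet library, under the minimum of 50. The medians were 0.66 in conventional dendritic cell-like cells and 1.04 in macrophage-like cells, against -0.06 in CD4+ T cells and -0.24 in B-like cells.

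Of 18 proliferation genes 16 were lower in WD conventional dendritic cell-like cells (median -0.83), with Stmn1 at -0.78, Ccnb2 at -1.46, Ube2c at -1.29 and Hmgb2 at -0.45. Cholesterol synthesis genes were lower at -0.40 (14 of 16), with Fdft1, the squalene synthase, at -2.30 (15 and 5 UMIs). The foam cell list was higher at 0.24, with the fatty acid binding protein Fabp5 at 1.26 (194 and 840 UMIs, ratio 2.40, 2.05 to 2.82), Abcg1 at 0.76 and Lgals3 at 0.27 but Cd36 at -1.03. Il1b (0.79; 1045 and 3264 UMIs, ratio 1.73, 1.61 to 1.86) and Ccl4 (0.95) were higher, yet the inflammatory macrophage list to which they belong had a median of -0.22, with Cxcl10 at -1.54, Cxcl1 at -2.09 and Il6 at -1.35. Nuclear factor kappa B genes were higher at 0.24 (Relb 0.92, Traf1 0.57), the T cell receptor list was lower at -0.32 (16 of 16; Cd2 -0.91, Cd247 -0.88) but within its random range at -0.13 without cells of 2 lineages, which were 30.6% and 14.8% of this class. The myeloid free RNA list stood at 0.19, although Lyz2 was at -0.65 and Pf4 at -4.17. Thinning brought the proliferation list to -0.23, the cholesterol synthesis list to -0.15, the foam cell list to 0.12 and the inflammatory macrophage list to -0.15, all within their random ranges, and turned the myeloid list to -0.11 and Cd36 to 0.25. Lyz1 was 11.4-fold higher in the chow diet library (8.94 to 14.6; 28 and 20 cells). Car2 (4.37), Igfbp6 (2.85) and Lepr (3.24, with 74 of 91 WD UMIs in 1 cell) were higher in the WD library, and Cxcl9 (-2.55), Il12b (-2.18), Tnfsf8 (-2.16), Atr (-1.90) and Map4k2 (-1.81) lower, of which Cxcl9, Il12b and Tnfsf8 rested mostly on 1 chow diet cell. The other 21 lists lay within their random ranges, between -0.20 and 0.27.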

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

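For the results weighed here, the tests of free RNA, B cell progenitors, a shift of the whole library, CD8 T cells without a Cd8 UMI and single cells were chosen only after the results were seen.

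Immature cells with Dntt held 23.9% of the chow diet library and 10.7% of the WD library. Free RNA of such cells would reach all clusters alike. A Dntt UMI was found in 1.49% of cells of the largest B-like cluster, though in 14.3% and 22% of the 2 small ones. Free RNA spread alike over clusters was therefore set aside as the source of the Dntt clusters. Over all B-like cells, however, a Dntt UMI was found in 8.77% of chow diet and 3.00% of WD cells. A part of free RNA in the difference between libraries was not tested. The 89.6% of Dntt cluster cells with a Dntt UMI is no test, since these clusters were set apart by that gene. B cell progenitors were set aside, since a UMI of a B progenitor gene was found in 5.53% of the Dntt clusters. Thymic tissue collected with some aortas is a candidate explanation: the share of cells with a UMI of a thymocyte gene was at the median 60.2 times that of T-like cells. Rag2 was found in 22.1% of Dntt cluster cells and 0 of 786 T-like cells, taken as 3 cells for the ratio, and Arpp21 in 74.7% and 1.15%. The ratios were uneven, from 3.02 for Cd1d1 and 3.175 for Themis to 96.7 for Aqp11. Such genes would also mark immature T cells resident in the aorta, and a sort for CD45 does not remove thymocytes. Diet cannot be told from the collection of tissue with 1 library per diet.

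Type I interferon genes were higher in conventional dendritic cell-like and macrophage-like cells of the WD library. A shift of the whole library was set aside, since the list stood at -0.24 in B-like cells. Without the 5% of cells with the most interferon UMIs the median remained at 0.47 in conventional dendritic cell-like cells and 0.83 in macrophage-like cells, so a few cells do not carry it, and without cells with a Siglech UMI it remained at 0.63, so plasmacytoid cells do not either. Median list UMIs per 10000 were 11.01 and 15.2 in conventional dendritic cell-like cells and 13.9 and 25.8 in macrophage-like cells. Other myeloid clusters were not read for this list, and cells were not weighted by cluster within the dendritic class. Whether diet or the handling of 1 pool caused the higher list cannot be told with 1 library per diet.

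CD4+ T cells of the WD library were higher in naive and cytotoxic genes and lower in activated genes. With WD cells weighted to the chow diet cluster shares the naive list moved from 0.46 to 0.33 and the activated list from -0.61 to -0.36. The shares of these clusters alone therefore do not account for either list. Makeup within the clusters, including any thymocytes among these cells, was not weighted and stays open. The subgroup with Dapl1 held 23.1% and 16.5% of CD4+ T cells and that with Ccr7 13.5% and 22.8%. The weighted cytotoxic list stood at 0.35 and with 1 member left out ran from 0.24 to 0.70, which leaves makeup open. Its values of -0.014 with whole subclusters and -0.41 without cluster 7 do not decide this. Both settings leave out cells that were grouped by genes of this list, which lowers its median by selection. Single cells were set aside, since without the top cell of each gene the medians were 0.49, -0.40 and 0.70. CD8 T cells without a Cd8 UMI would put Cd8a or Cd8b1 in as large a part of the Cd4-positive cells of cluster 7 as of its other cells, but the shares were 43.3% (13 of 30) and 87.7% (228 of 260), so most Cd4-positive cells there are not likely to be such cells. Diet cannot be told from other differences between the pools with 1 library per diet.

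Other results differed between classes by amounts that were not tested. The naive and central memory T list was 0.71 higher in CD4+ T cells than in B-like cells. For the foam cell and Trem2 macrophage list the difference from conventional dendritic cell-like cells was -0.52 in T-like cells and -0.95 in CD4+ T cells. The inflammatory macrophage list differed by 0.51 between T-like and conventional dendritic cell-like cells. Myeloid transcripts abundant in free RNA differed by 0.94 between T-like and B-like cells, by 0.90 between CD4+ T and B-like cells, and by -0.64 between B-like and conventional dendritic cell-like cells.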

How the results depend on the processing

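Chosen only after the results were seen were the settings without the Dntt clusters or with them counted as T-like, without cells of 2 lineages, without the top cell of each gene and without cluster 7. No paired analysis was possible because each diet has 1 library. Shares are given for the chow diet and the WD library and list and gene values as log2 ratios. Class shares also move where clusters are joined, split or named otherwise, as with the NK-like, macrophage-like and conventional dendritic cell-like shares above. Beyond this, the cause was not tested for any value that moved or turned.

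Filters moved some class shares. With a mitochondrial limit of 5% NK-like cells held 5.31% and 6.03%, Dntt clusters 20.3% of the chow diet library, and unnamed other clusters 2.89% and 1.03%, while Slpi in B-like cells turned to 4.02. With no mitochondrial limit NK-like cells held 5.09% and 5.50%, Dntt clusters 20.9% of the chow diet library, and unnamed other clusters 4.87% of the WD library. With Scrublet calls kept the NK-like share was 3.79% and 3.40%, the Dntt share 21.0% in the chow diet library, and the T-like share 28.8% and the unnamed other share 5.00% in the WD library.

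Clustering moved shares as well. At a resolution of 0.5 T-like cells held 31.4% and 31.0%, conventional dendritic cell-like cells 2.35% and 1.99%, unnamed other clusters 13.3% and 14.6%, and B-like cells 25.04% of the WD library. A resolution of 1.5 gave unnamed other clusters 3.14% and 4.23%. With 1000 variable genes NK-like cells held 3.59% and 2.92%, macrophage-like cells 8.74% and 13.6%, unnamed other clusters 2.91% and 0.924%, Dntt clusters 21.0% of the chow diet library and T-like cells 29.6% of the WD library. With 4000 variable genes Dntt clusters held 20.5% and 9.43%, and in the WD library NK-like cells 2.67%, T-like cells 29.7% and unnamed other clusters 4.96%. Another seed gave the Dntt clusters 21.1% and the unnamed other clusters 9.87% of the chow diet library; among CD4+ T cells the subgroups with Dapl1 and with Ccr7 were both matched to 1 subcluster that held 34.6% and 39.2%.

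With a subcluster resolution of 0.5 both subgroups were again matched to 1 subcluster that held 36.5% and 40.5%, and the subgroup with Tnfrsf4 held 30.4% of the WD library's CD4+ T cells. At 1.2 the subcluster matched to that with Dapl1 held 0% and 0%, and in the WD library the subgroup with Ccr7 held 10.1% and that with Tnfrsf4 32.9%. Clustering without the named genes put the last at 34.2% in the WD library.

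Taking CD4+ T cells by whole subclusters gave shares of 11.3% and 8.02% of leukocytes and 40.9% and 30.6% of T-like cells. It put the T helper 1 list at -0.15, the activated list at -0.38, the cytotoxic list at -0.014, the homing list at -0.11 and the B-1 list at -0.078. Gzma turned to -1.45, Ccl4 to -1.33, Ccl5 to -0.014, Slfn1 to -0.0009, Cxcl10 to 1.11, Hist1h2ap to 0.40, Ikzf2 to 0.19 and Cd74 to -0.14. The marker gate put the regulatory T cell list at -0.037, T helper 17 at 0.33, T helper 2 at -0.10, activated at -0.27, immediate early at -0.30, proliferation at 0.59, homing at 0.18 and foam cell at -0.10. Under it Retnla stood at -0.28, Ccl4 at -1.24, Areg at 0.28, Lef1 at -0.17, Tmem176b at 0.14 and Ctsz at 0.74.

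Without cluster 7 the CD4+ T cell lists stood at -0.90 (regulatory T cell), -0.30 (T helper 1), -0.065 (T helper 17), 0.091 (T helper 2), -0.41 (cytotoxic), 0.18 (immediate early) and 0.17 (proliferation), and Gzma at -1.68. Without the Dntt clusters B-like cells held 25.2% and 30.8%, T-like cells 36.4% and 29.4%, and in the chow diet library conventional dendritic cell-like cells 12.5%, unnamed other clusters 9.72% and CD4+ T cells 7.66%. With the Dntt clusters counted as T-like, CD4+ T cells were 13.04% and 11.2% of T-like cells.

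Without cells of 2 lineages conventional dendritic cell-like cells held 7.14% of the chow diet library. In CD4+ T cells this put T helper 17 at -0.073, T helper 2 at -0.034, proliferation at 0.41, the myeloid list at -0.82 and Retnla at -0.32. In B-like cells Slpi turned to 3.83 and Ifng to 2.93. In T-like cells MHC class II turned to -0.16, the myeloid list to -0.11, Cd74 to -0.049 and Ube2c to 0.0047. In Dntt cells the inflammatory macrophage list turned to -0.14, MHC class II to -1.03 and the myeloid list to -0.37.

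With the top cell of each gene left out in each library, T helper 2 stood at 0.19 in CD4+ T cells, activated at -0.40, type I interferon at 0.31, proliferation at 0.10 and the myeloid list at -0.77. Without the top cell of the higher library Retnla turned to -0.28 and Cd74 to -0.058 in CD4+ T cells, Jchain to -1.05, Slpi to 3.99 and Ifng to 0.064 in B-like cells, Il17f to 0.92, Gzma to 0.23 and Ube2c to 0.0024 in T-like cells, and Il12b to 1.37 in conventional dendritic cell-like cells.

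The mean over cells put regulatory T cell genes at -0.14, naive at 0.21, activated at -0.21, proliferation at 0.024, homing at 0.0065 and B-1 at -0.28 in CD4+ T cells, the myeloid list at -0.028 in conventional dendritic cell-like cells, and Gzma at -0.21 in B-like cells. Thinning cells to 1000 UMIs before summing put T helper 17 at -0.16, follicular helper T at 0.56, activated at -0.23, cytotoxic at 1.53, nuclear factor kappa B at 0.33, type I interferon at -0.70, foam cell at -0.18, inflammatory macrophage at 0.40 and B-1 at -0.12 in CD4+ T cells. There Il21r turned to -0.16, AY036118 to 0.12 and Stat4 to 0.13. In B-like cells thinning turned the T cell receptor list to 0.19, Mcm4 to -0.66, Jchain to -0.021, Cd3g to 0.33 and Gzma to -0.047. In T-like cells the regulatory T cell list turned to 0.043, immediate early to 0.0011, inflammatory macrophage to -0.054, myeloid to -0.017, Kcnk5 to -0.11, Il1b to -0.91, Klrg1 to 0.043 and Ccl3 to -0.0098, and in conventional dendritic cell-like cells the myeloid list turned to -0.11, Irf7 to -0.072 and Cd36 to 0.25. In Dntt cells the mean over cells turned MHC class II to -0.11, and thinning turned it to -0.048 and the inflammatory macrophage list to -0.049. In macrophage-like cells the inflammatory macrophage list turned to 0.10 with the mean over cells, to 0.14 with thinning and to 0.014 without the top cell of each gene, and stood at -0.092 without cells of 2 lineages.

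For the lineage factors, thinning to 1500 UMIs put Tbx21 at 7.69% of WD CD4+ T cells; without thinning Tbx21 stood at 8.86% and Bcl6 at 6.33% there and Gata3 at 34.6% and 17.7%. A minimum of 5 UMIs put T helper 2 at -1.52, and a minimum of 20 put T helper 17 at -0.21, T helper 2 at -1.52 and inflammatory macrophage at -0.68.

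Further values of single genes, and of lists outside CD4+ T cells, left their main interval or range and are not given singly, such as Ccl5 at 1.72 and Nkg7 at 0.79 in CD4+ T cells with the mean over cells. Under the settings fixed in advance, 47 gene results moved in this way in CD4+ T cells, and 13 list results in T-like, 6 in conventional dendritic cell-like and 2 in B-like cells. Results that stayed within their main interval or range under these settings were 289 of 321 list results and 566 of 630 gene results in CD4+ T cells, 124 of 162 class shares, 20 of 22 and 18 of 20 CD4+ T cell shares among leukocytes and T-like cells, 55 of 60 lineage factor shares and 12 of 24 subgroup shares. In other classes those that stayed were 103 of 120 lists and 261 of 287 genes in T-like cells, 77 of 80 and 251 of 266 in B-like cells, and 72 of 80 and 279 of 301 in conventional dendritic cell-like cells. Under the settings added later 65 of 81 lists and 186 of 210 genes in CD4+ T cells and 27 of 34 class shares stayed.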

Other observations

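The readings of macrophage-like, ILC2-like and Dntt cells and of AY036118 were chosen only after the results were seen.

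Macrophage-like cells of the WD library, at 45 chow diet and 202 WD cells, were higher in type I interferon genes, with 17 of 18 higher and a median of 1.04. Irf7, the factor that sustains the response, had 25 and 179 UMIs (1.08), Rtp4 13 and 148 (1.74), Bst2 stood at 0.83, and Herc6 at 3.03 with its WD UMIs spread over 24 cells. Ifit1 stood at 3.38 (3 and 112 UMIs) and at 1.87 without its top cell. Spp1, which encodes osteopontin and marks lipid-laden macrophages, had 43 and 809 UMIs (2.48), with 339 in 1 cell and 1.70 without it. Ly6a, an interferon-induced surface protein, stood at 2.57, while Lyz1 (-1.89) and the collagenase Mmp13 (-3.01) were lower in the WD library. The foam cell list stood at 0.28 (12 of 17 higher) and the immediate early and dissociation-induced list at 0.26 (15 of 21 higher). The inflammatory macrophage list was lower at -0.31 (9 of 14 lower) but turned to 0.14 with thinning, and the inhibitory receptor list was lower at -0.99 (3 of 3).

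ILC2-like cells, at 42 and 94, were higher in immediate early and dissociation-induced genes in the WD library, with 20 of 21 higher and a median of 0.43, led by Fos (135 and 555 UMIs, 1.13) and Junb (0.43). Their activated list was lower at -0.34. Transcripts of other cells were higher there too, with stromal transcripts abundant in free RNA at 4.03 (3 measured genes, 3 and 90 UMIs) and at 0.53 without the top cell of each gene, MHC class II genes at 0.88 (7 of 7) and the inflammatory macrophage list at 0.78. Dntt cells of the WD library were higher in cholesterol synthesis genes (median 0.66, 16 of 17), among them Hmgcs1 (1.17) and Insig1 (1.04), an enzyme and a sterol sensor of the pathway. The Dntt cells also differed in makeup and depth, with cluster 14, led by Dut and Hells, at 15.0% and 22.6% of them, cluster 3, led by Ccr9, at 53.1% and 44.3%, the proliferation list at 0.09 and median depths of 3059 and 4035 UMIs. The cholesterol synthesis genes were not told apart from this makeup. Myeloid transcripts abundant in free RNA (1.85, 14 of 14 higher), the inflammatory macrophage list (2.23, 11 of 11) and MHC class II genes (0.47, 7 of 8), which mark other cell types, were also higher in these cells and stood at -0.37, -0.14 and -1.03 without cells of 2 lineages. The cholesterol synthesis list was lower at -0.40 in conventional dendritic cell-like cells; the difference between these classes was not tested. Cells with both a Cd4 and a Cd8a or Cd8b1 UMI made up 52.1% and 44.8% of the Dntt clusters.

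AY036118, a transcript of the ribosomal RNA region, was lower in the WD library in the 7 classes read: -1.23 in CD4+ T cells, -2.10 in T-like, -1.99 in B-like, -2.18 in conventional dendritic cell-like, -1.94 in macrophage-like, -1.60 in ILC2-like and -2.21 in Dntt cells. A difference of this size in unrelated classes may come from library preparation, although thinning of CD4+ T cells gave 0.12 for AY036118.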
